A study of Mus musculus with 6 samples.

How the data were processed

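Small RNA libraries from vesicles of primary mouse hepatocytes, 3 control and 3 treated with 600 µM palmitic acid, were made with a NEBNext Multiplex small RNA kit from Trizol-extracted RNA, per the labels' protocols. The submitters' processing notes name Bowtie2, bedtools and the builds GRCm38 and mm10, without versions or roles; the miRNA annotation and the counting rule are not given in the sources used here. The series has 1 table of 1976 mature mouse miRNAs by 6 libraries, with no repeated name and no column of another sample. Groups and replicate numbers were taken from the labels.

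The table is named as raw counts, but the deposited values are on a log2 scale and are not whole numbers. From the values, each is log2(adjusted count + 1). The adjusted counts are matched by a negative binomial quantile adjustment to a common library size, with 1 dispersion (fitted at 1.38) and 1 mean per miRNA. The median absolute difference between the deposited and refitted values was 2.2e-04. No label states this step. Of the 1976 rows, 918 are at 0 in all 6 libraries and 1058 hold a value above 0. In 108 rows no read was recovered from any of the 6 libraries although small positive control values stand there. Libraries not analysed here may have entered the adjustment, so the common library size, the factors and the fold changes on the deposited scale may be set relative to more than these 6 libraries. The adjustment was inverted to recover reads. Of the values tested, 98.7% came out as whole reads within 0.0015 on the log2 scale, where neighbouring read numbers were at least 0.02 apart. On simulated data of 1058 rows the inversion recovered 98.8% of read numbers within 0.2%.

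Recovered totals ran from 95181 to 798552 reads per library. The fitted library factors were 0.322, 0.368 and 0.463 in control replicates 1, 2 and 3 and 2.05, 2.86 and 1.68 with palmitic acid, so that 1 read was worth more in controls, with a 5.64-fold ratio of the geometric means. Without the arms of miR-122 and miR-122b, control libraries held 29350, 80754 and 52626 reads and palmitic acid libraries 676300, 671884 and 534083. Reads were found for 238, 243 and 242 miRNAs in controls and for 610, 640 and 484 with palmitic acid. The deposited value of 1 read was 1.54, 1.48 and 1.37 in controls and 0.46, 0.28 and 0.59 with palmitic acid, so low values are less precise in controls. Shares and detected miRNAs were computed from recovered reads, fold changes from deposited values.

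A count-based quasi-likelihood test had been planned before the data were examined. Because the unit is log2, limma 3.58.1 (R 4.3.3) with a mean-variance trend was used on the deposited log2 values instead, with a group term only, on miRNAs with an adjusted count of at least 10 in at least 3 libraries (181 miRNAs), with Benjamini-Hochberg adjustment at 0.05. All tests are two-sided. A fold change is on the log2(adjusted count + 1) scale and understates the change of low miRNAs. Where no control read was recovered, a lower bound was computed against 3 reads over the control group, equal to 2.60 adjusted counts. On data simulated for this comparison (181 miRNAs, 90 of them changed), 8% of changes of 1, 48.3% of changes of 2 and 80.6% of changes of 4 on the log2 scale were recovered, and 4.26% of calls were unchanged miRNAs. Shares, detected miRNAs and miR-30b-5p were also compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3.

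miRNAs were named by a rule fixed at the same time: miR-30b-5p and the measured miR-30 family, the 10 with the highest mean abundance, per direction the 8 largest and the 5 most abundant changes among passing miRNAs with separated groups, and up to 4 of the most abundant members of each fixed list. Of the 79 so named, 35 came from parts of the rule other than the lists. The 30 lists, also fixed beforehand, hold cell type markers (hepatocyte, biliary or other epithelial, endothelial, immune and Kupffer cell, stellate cell and fibroblast, striated muscle, erythroid, neuronal), families and clusters, and miRNAs linked to metabolism, inflammation, p53, hypoxia, endothelial function and insulin signalling. Lists with at least 3 tested members (17) were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and the fry test as alternatives. On simulated lists, camera found the lists raised and lowered by 3 on the log2 scale and not the unchanged one (adjusted p = 0.407). The simulated miRNAs were drawn independently, so false calls from correlated members were not covered. Arm ratios used 0.5 added to each adjusted count and a mean of at least 10 per arm; on simulated data of the 24 hairpins, 50% of ratios changed by 4 were recovered and 0 unchanged hairpins were called.

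Of the 1976 rows, 1901 were matched by name to hairpins in the GENCODE and RefSeq annotations of GRCm38, which gave positions and host genes. GC content was that of the hairpin side that holds an arm, or of the whole hairpin where a name gives no arm. Mature sequences were not used here. Alternatives covered other scalings, a voom fit of the recovered reads, filters, a replicate block, a threshold of 0.1, leaving out each library, and, chosen after the data were seen, thinning of reads (20 draws), a pseudocount of 5, centring, changes relative to the median, and removal of a GC trend. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.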

Results

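Small RNA was sequenced from extracellular vesicles, the membrane-bound particles that cells release, of primary hepatocytes from wild-type C57BL/6J mice. The labels call the vesicles exosomes. The 6 libraries form 2 groups of 3: vesicles from control cells given palmitic acid at 0 µM, and vesicles from cells given 600 µM. Palmitic acid is a saturated fatty acid used to load hepatocytes with lipid in culture. The title of the series names hepatic steatosis, endothelial dysfunction and miR-30b-5p, so the comparison asks which vesicle miRNAs differ when the hepatocytes are lipid-loaded. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Reads recovered from the deposited values totalled 95181, 657347 and 252302 in control replicates 1, 2 and 3, and 798552, 761341 and 613241 in palmitic acid replicates 1, 2 and 3. No replicates of a group agreed within sampling noise, since the chi-square per degree of freedom between them ran from 78.9 to 479.

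miR-122-5p, the liver-enriched miRNA that dominates hepatocytes, took most of the control reads and a small part of the palmitic acid reads. Together with miR-122b-3p it held 78.7% ± 9.29 (SD, n = 3) of control reads and 13.3% ± 1.82 (SD, n = 3) of palmitic acid reads. The miR-122b hairpin (GRCm38 chromosome 18, 65248863 to 65248921) lies inside the miR-122 hairpin (65248861 to 65248926), so reads of the pair cannot be separated with certainty and are given together. Palmitic acid libraries held 16.3% ± 2.96 miR-21a-5p against 0.633% ± 0.384 in controls, 9.68% ± 1.85 let-7f-5p against 0.365% ± 0.209, and 5.70% ± 2.14 miR-30a-5p against 0.136% ± 0.0888 (SD, n = 3 each). miR-148a-3p, a second abundant liver miRNA, held 20.7% ± 8.60 against 5.81% ± 1.73, whereas miR-6239 held 0.359% ± 0.0448 against 4.70% ± 3.43.

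For each of these shares, as for miR-122 with miR-122b-3p, every palmitic acid library lay on the same side of every control library, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Per library, the share of miR-122-5p with miR-122b-3p was 69.2% (95% Clopper-Pearson interval 68.9 to 69.4), 87.7% (87.6 to 87.8) and 79.1% (79.0 to 79.3) in controls. It was 15.3% (15.2 to 15.4), 11.7% (11.7 to 11.8) and 12.9% (12.8 to 12.97) with palmitic acid. These intervals, and the floors given for miRNAs without control reads, cover counting error only, since reads copied by PCR are not independent molecules. The 10 miRNAs with the highest mean abundance over all 6 libraries, a fixed set that is not the leading set of each library, held 91.4% ± 5.87 of control reads and 82.3% ± 2.74 of palmitic acid reads (SD, n = 3, exact permutation p = 0.1). At the common depth of the shallowest library, 197 ± 42.0 miRNAs were detected in controls and 327 ± 26.6 with palmitic acid (SD, n = 3, exact permutation p = 0.1), a difference of 129.7. It became 213 without control replicate 1, which sets that depth, 52.2 when 5 reads were required and 337 at full depth. That depth is common for all reads together, not for miRNAs other than miR-122. With miR-122-5p and miR-122b-3p at 69.2% to 87.7% of control reads, fewer reads were left for other miRNAs in controls. The difference in detected miRNAs is therefore not separate from the difference in the miR-122 share. Nor are the higher shares of other miRNAs, as the shares of a library add up to its total. Of reads other than miR-122 and miR-122b, miR-148a-3p held 5552 of 29350, 49419 of 80754 and 10263 of 52626 in controls. With palmitic acid it held 137377 of 676300, 110020 of 671884 and 187215 of 534083, so the groups overlapped. miR-21a-5p, at 997, 1894 and 1421 of the same control reads and 146719, 134133 and 79148 with palmitic acid, did not overlap.

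**Figure D1:**
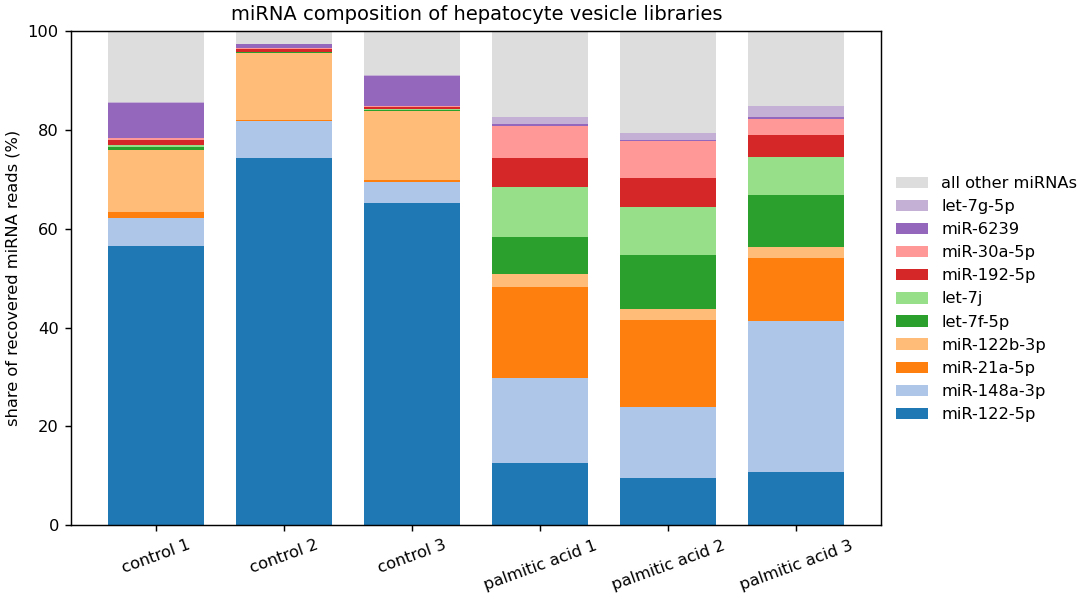
Share of recovered miRNA reads (percent, vertical axis) taken in each library by the 10 miRNAs with the highest mean abundance over all 6 libraries, and by all others, 1 stacked bar per library. The 2 miR-122 segments, miR-122-5p and miR-122b-3p, add up to between 69.2% and 87.7% in controls and between 11.7% and 15.3% with palmitic acid.

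miR-30b-5p, the miRNA named in the title of the series, was higher in palmitic acid vesicles by 4.67 on the log2 scale (SE 0.58, 95% interval 3.32 to 6.02, limma adjusted p = 2.9e-04), which is 25.5-fold on the log2(adjusted count + 1) scale. Its deposited log2 values were 4.09, 5.09 and 3.83 in controls and 9.14, 8.98 and 8.88 with palmitic acid, so it was higher in 3 of 3 palmitic acid libraries. These values rested on 5, 12 and 6 recovered reads in controls and on 1156, 1447 and 794 reads with palmitic acid. In RPM of recovered reads that was 31.5 ± 18.4 against 1548 ± 315 (SD, n = 3), and the exact permutation test of the log2 values gave p = 0.1, the smallest possible. It ranked 27 by fold change and 28 by p among the 181 tested miRNAs. The Mir30b hairpin lies on GRCm38 chromosome 15, 68337415 to 68337510, minus strand, in an exon of the long non-coding transcript Gm26621.

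Of the 9 tested members of the miR-30 family, 4 rose, 0 fell and 5 passed in neither direction, against 2 higher and 4 lower relative to the median tested miRNA. Upper-quartile scaling and centring each gave 4 higher and 2 lower. miR-30a-5p rose by 4.52 (SE 0.47, adjusted p = 9.8e-05) and was far more abundant, with 51994, 55705 and 20028 reads in the palmitic acid libraries. miR-30c-5p rose by 2.95 (SE 0.47, adjusted p = 0.00114) and miR-30e-5p by 2.42 (SE 0.61, adjusted p = 0.00941). Neither passed relative to the median (1.01 and 0.48), and miR-30e-5p was not past the threshold without palmitic acid replicate 1 (adjusted p = 0.0624; 0.00383 to 0.534 over its alternatives). miR-30d-5p, whose hairpin (68341208 to 68341289) neighbours that of miR-30b on chromosome 15, differed by 0.12 (SE 0.40, 95% interval -0.81 to 1.05, adjusted p = 0.811), and by -1.82 relative to the median. The others were miR-30e-3p at -1.20, miR-30c-2-3p at 0.90, miR-30f at -1.54 (-1.74 without control replicate 3, adjusted p = 0.0480; 0.00318 to 0.541 over its alternatives) and miR-30a-3p at -0.41 (-1.47 without control replicate 1, adjusted p = 0.0181; 0.0181 to 0.971). The Mir30f and Mir30e hairpins occupy the same bases on opposite strands, and members of the family differ by few bases, so reads may have been split between them and their single values are uncertain.

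Across all 181 tested miRNAs, 76 were higher and 26 lower in palmitic acid vesicles (limma, Benjamini-Hochberg adjusted p below 0.05), 79 passed in neither direction, and 112 had an unadjusted p below 0.05. The largest fitted rises were in miR-17-5p, a member of the growth-linked miR-17 to miR-92 cluster, by 6.83 (SE 0.63), in miR-29c-3p, of a family that targets collagen transcripts, by 6.29 (SE 0.80), and in miR-378b by 6.20 (SE 1.22). This order rests in part on the value given to 0 reads: miR-17-5p and miR-19b-3p had no control read, and miR-29c-3p, miR-374b-5p, miR-378b and miR-98-5p had none in at least 1 control library. miR-374b-5p (5.97, SE 0.77), miR-7a-5p (5.91, SE 0.59), miR-19b-3p (5.81, SE 0.55), miR-7b-5p (5.71, SE 0.50) and miR-98-5p (5.62, SE 0.998) followed. miR-7a-5p and miR-7b-5p, like members of the miR-378 family, have near-identical sequences, so their single values are uncertain. Among abundant miRNAs, miR-21a-5p, often raised in liver injury, rose by 3.89 (SE 0.47), let-7j by 4.64 (SE 0.43), let-7f-5p by 3.88 (SE 0.47) and let-7g-5p by 2.61 (SE 0.46), the last not past the threshold relative to the median (0.67, adjusted p = 0.251; 2.4e-04 to 0.251 over its alternatives). miR-192-5p, a hepatocyte and epithelial miRNA, rose by 1.94 (SE 0.61, adjusted p = 0.0259). This call was lost in 10 of its 20 alternatives (adjusted p 1.2e-04 to 1), among them leaving out control replicate 1 (adjusted p = 0.0852) or 3 (0.0834) or palmitic acid replicate 1 (0.0867), 2 (0.0602) or 3 (0.0728). miR-148a-3p did not pass (0.83, SE 0.92, adjusted p = 0.453), although without control replicate 2 it reached 1.75 (adjusted p = 0.0254; 0.00157 to 0.966 over its alternatives).

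The largest falls were in miR-423-3p (-6.01, SE 0.51), in miR-206-3p, a striated muscle miRNA (-5.06, SE 0.80), in miR-674-3p (-4.37, SE 0.95) and in miR-486a-5p, an erythroid miRNA (-4.20, SE 0.95). miR-7075-3p (-4.20, SE 1.05), miR-6239 (-4.16, SE 0.47), miR-139-5p (-4.00, SE 0.91) and miR-128-3p (-3.86, SE 0.86) also fell. miR-122-5p fell by 3.56 (SE 0.98, adjusted p = 0.0141) and miR-122b-3p by 3.46 (SE 0.75, adjusted p = 0.00477). The miR-122-5p call was lost without any 1 of palmitic acid replicates 1, 2 and 3 (adjusted p = 0.0778, 0.0892 and 0.0790), with the log2 change between -3.77 and -3.29 in those fits, and with no filter on low values (adjusted p = 0.0558). Over all its alternatives the log2 change of miR-122-5p ran from -5.50 to -2.58 and its adjusted p from 1.6e-05 to 0.105. Of the 20 alternatives 6 ended the call, among them the replicate block (adjusted p = 0.105). miR-99a-5p fell by 1.79 (SE 0.40) and let-7c-5p by 1.84 (SE 0.47). Their hairpins Mir99a (77598936 to 77599000) and Mirlet7c-1 (77599657 to 77599750) are neighbours on chromosome 16 in an intron of Mir99ahg. With library totals as the scale, miR-99a-5p (-0.81, adjusted p = 0.257), let-7c-5p (-0.86, adjusted p = 0.199) and miR-128-3p (-2.94, adjusted p = 0.0730) no longer passed, each at its highest adjusted p over the alternatives, from lowest values of 3.2e-04, 3.9e-04 and 9.0e-04. With no filter, let-7c-5p did not pass either (adjusted p = 0.0732). After a GC trend was removed, miR-7075-3p (-2.22, adjusted p = 0.110; 0.00121 to 0.122 over its alternatives) and miR-486a-5p (-2.45, adjusted p = 0.0503; 7.4e-04 to 0.0560) did not pass.

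The median log2 change of the 181 miRNAs was 1.94, and it lay between 1.15 and 2.80 under the other scalings tried, so the number of miRNAs that stand above 0 depends on the scale. Relative to that median, 48 miRNAs were higher and 59 lower, against 76 and 26 as deposited; library totals gave 96 and 10, and centring each library on its median tested miRNA gave 65 and 40. Relative to the median, miR-30b-5p stood at 2.73, miR-21a-5p at 1.95, miR-17-5p at 4.90, miR-122-5p at -5.50 and miR-423-3p at -7.95. In the tested miRNAs, 123 had fully separated groups, where chance gives 10%. No read was recovered from any control library for 17 tested miRNAs, and all 17 rose. Their fitted log2 changes, SEs and p-values depend on the value given to 0 reads. Their control values are set by the adjustment, so the spread of these is not a measured one between libraries. A miRNA without a control read passes the filter only where all 3 palmitic acid libraries reach an adjusted count of 10. The direction and the separated groups of these 17, which are among the 123, were thus fixed by the filter. Against a floor of 3 reads over the control group, miR-17-5p was at least 58.8-fold higher, miR-19b-3p at least 30.2-fold, miR-96-5p at least 21.5-fold and miR-34a-5p, a p53 target, at least 19.9-fold. Log2 changes correlated with the GC content of the hairpin side that holds each arm (Spearman rho = -0.38, Pearson r = -0.38, across 174 miRNAs, which are not independent replicates; permutation p = 1e-05, the smallest that the resamples can give).

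**Figure D2:**
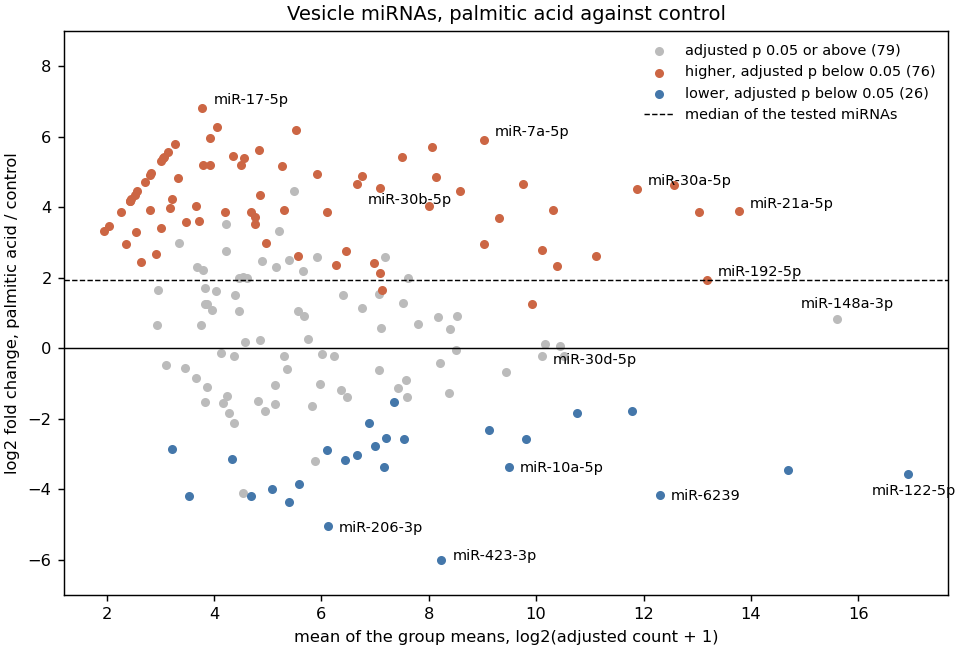
Log2 fold change, palmitic acid over control (vertical axis), against the mean of both group means in log2(adjusted count + 1) (horizontal axis), 1 point per tested miRNA, coloured by direction where the limma adjusted p was below 0.05. The dashed line is the median log2 change of 1.94; the 76 higher and 26 lower miRNAs become 48 and 59 when changes are taken relative to it.

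Markers of hepatocytes and of other cell types that vesicle preparations could hold were compared as fixed lists. Among the rises counted next, miR-192-3p and miR-96-5p had no control read, so the filter fixed their direction. Among 7 tested hepatocyte miRNAs, 2 rose (miR-192-5p and its 3p arm miR-192-3p), 1 fell (miR-122-5p) and 4 passed in neither direction, such as miR-194-5p (-0.23, adjusted p = 0.720), whereas 1 was higher and 2 lower relative to the median, and 1 higher and 1 lower with upper-quartile scaling or centring. Of 3 tested epithelial miRNAs, which share a cluster on chromosome 6, miR-96-5p rose by 5.40 (SE 0.44) and miR-182-5p by 2.79 (SE 0.45), and miR-183-5p stood at 1.51 (adjusted p = 0.0798, and 0.0264 without control replicate 2; 0.0264 to 0.607 over its alternatives); relative to the median tested miRNA, miR-96-5p alone passed. The single tested striated muscle miRNA, miR-206-3p, fell, as did 1 of 2 erythroid miRNAs, miR-486a-5p, beside miR-451a at -3.20 (adjusted p = 0.0764, and 0.0475 without control replicate 3; 0.0114 to 0.269 over its alternatives). Of 2 immune and Kupffer cell miRNAs, miR-146a-5p, an inhibitor of NF-kB signalling, fell by 2.13 (adjusted p = 0.0332). That call was lost in 8 of 20 alternatives (adjusted p 0.001 to 0.331), among them library totals (0.331) and the fits without palmitic acid replicate 1 (0.0665), 2 (0.0924) or 3 (0.0912) and without control replicate 1 (0.0850) or 2 (0.0891). miR-155-5p stood at 2.23 (adjusted p = 0.176, and 3.76 with 0.00727 without control replicate 1; 0.00727 to 0.864 over its alternatives). Neither endothelial miRNA passed (miR-126a-3p at 0.07, miR-126b-5p at -0.18), although both were lower relative to the median tested miRNA (-1.87 and -2.11). The Mir126b hairpin (chromosome 2, 26591363 to 26591420) lies inside the Mir126a hairpin (26591357 to 26591429) on the opposite strand. The 2 are thus not separate markers with certainty. None of 3 stellate cell and fibroblast miRNAs passed (miR-143-3p at -0.89, miR-199a-3p at -1.63, miR-199b-3p at -1.50, with a camera adjusted p = 0.341), although all 3 were lower relative to the median. Without control replicate 2, miR-199a-3p (-2.13, adjusted p = 0.0227, with 0.00469 to 0.645 over its alternatives) and miR-199b-3p (-2.11, adjusted p = 0.0325, with 0.0117 to 0.695) passed. Reads of miR-199a-3p and miR-199b-3p ran in parallel, with 58, 18 and 51 against 31, 7 and 25 in control replicates 1, 2 and 3. With palmitic acid they were 69, 87 and 51 against 34, 43 and 27. The 2 may thus hold 1 signal and are not separate markers with certainty. The 1 tested neuronal marker, miR-7b-5p, rose, but its value is uncertain beside the near-identical miR-7a-5p. miR-9-5p of the same list did not pass the filter and went the other way. It had 257, 0 and 92 recovered reads in control replicates 1, 2 and 3 and 10, 0 and 1 with palmitic acid.

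In the miR-10, miR-99, miR-100 and miR-125a and b family, 6 of 8 tested members fell, 0 rose and 2 passed in neither direction, with a median of -2.66, whereas with library totals as the scale 1 was lower and 1 higher. miR-10a-5p, encoded on chromosome 11 (96317165 to 96317274), fell by 3.36 (SE 0.64, adjusted p = 0.00262), beside miR-99a-5p. miR-125a-5p fell by 2.56 (adjusted p = 0.0374). That call was lost in 10 of 20 alternatives, among them each fit without control replicate 2 (adjusted p = 0.0891) or 3 (0.0897, at -1.67) or a palmitic acid replicate (0.0889, 0.0822 and 0.0958 without 1, 2 and 3; 0.00313 to 0.202 over all). miR-99b-5p stood at -1.27 (adjusted p = 0.0815, and 0.0169 at -1.77 without control replicate 2; 0.00182 to 0.820 over its alternatives), and turned to 1.04 with the GC trend removed. The family was the 1 list of the 17 with at least 3 tested members that passed the camera test (adjusted p = 0.00358), and it did not pass with a correlation estimated from the data (adjusted p = 0.792; 0.00188 to 0.792 over its alternatives). The adjusted p of the other lists lay between 0.341 and 0.962. The family's median stayed negative under each scaling, between -4.60 and -1.69. The list counts both arms of miR-99b and of miR-125a, whose hairpins both lie in Spaca6, so its members are not all separate.

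The let-7 and miR-98 family split: of 12 tested members 5 rose, 3 fell and 4 passed in neither direction, whereas with library totals 6 were higher and 0 lower, and relative to the median 4 were higher and 6 lower. let-7i-5p rose by 3.92 (SE 0.60) beside let-7f-5p, let-7g-5p, let-7j and miR-98-5p, whereas let-7c-5p fell beside let-7b-5p and let-7d-3p, which are named after their values were seen. The family's median of 0.53 and mean of 1.12 were positive, but the median was -0.01 with upper-quartile scaling, -0.26 with centring and -1.41 relative to the median tested miRNA. The camera test, which compares the list with the other miRNAs, pointed down (adjusted p = 0.880). Members differ by 1 or a few bases, so assignment between them is uncertain. Of the rises that follow, those of miR-29c-5p, miR-17-5p and miR-19b-3p came without a control read, so the filter fixed their direction. In the miR-29 family 3 of 4 tested members rose, or 2 relative to the median (median 3.78, or 3.50 with miR-29c-5p at its bound). Among them, miR-29a-3p rose by 3.68 (SE 0.82) and did not pass relative to the median tested miRNA (1.75, adjusted p = 0.106; 4.7e-05 to 0.106 over its alternatives). miR-29b-3p stood at 3.32 (adjusted p = 0.0776, and 0.0244 without control replicate 1; 0.0244 to 0.440 over its alternatives). In the miR-17 to miR-92 clusters 4 of 8 rose and 0 fell, with miR-20a-5p by 5.40 (SE 1.30) on control reads of 0, 0 and 12, whereas 1 was lower with upper-quartile scaling or centring and 2 relative to the median, where miR-92a-3p turned from 0.55 to -1.39. The miR-20a-5p call was lost in a voom fit of the recovered reads (adjusted p = 0.0751) and with no filter (0.0582, with 3.1e-04 to 0.0751 over its alternatives). miR-93-5p stood at 4.47 (adjusted p = 0.0529) and passed in 7 of 20 alternatives, at 6.58 without control replicate 1 (adjusted p = 9.4e-04, with up to 0.270 over its alternatives). miR-25-3p stood at -1.14 (adjusted p = 0.140) and passed as lower in 4 of 20, at -1.62 without control replicate 3 (adjusted p = 0.0379, with 0.00318 to 0.873 over its alternatives). miR-23b-3p (3.86, SE 0.68) and miR-27b-3p (1.26, SE 0.34) were the 2 of 6 that rose in the miR-23, miR-27 and miR-24 clusters, where 1 was higher and 2 lower relative to the median. miR-27b-3p then stood at -0.68, and it was not past the threshold without palmitic acid replicate 1 (adjusted p = 0.0502) or 3 (0.0507; 0.0157 to 0.379 over its alternatives).

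**Figure D3:**
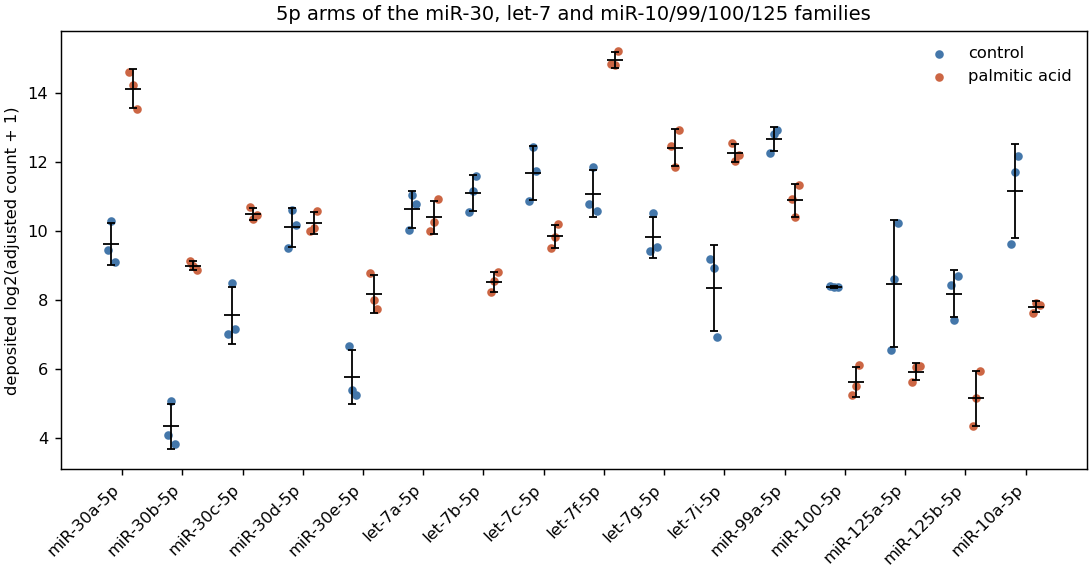
Deposited log2(adjusted count + 1) values (vertical axis) of 16 miRNAs from the miR-30, let-7 and miR-10, miR-99, miR-100 and miR-125a and b families (horizontal axis), with 1 point per library and the mean ± SD of each group of 3. miR-30b-5p lay between 3.83 and 5.09 in controls and between 8.88 and 9.14 with palmitic acid, and miR-30d-5p overlapped; relative to the median tested miRNA, miR-30d-5p turned to -1.82.

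In the remaining families and clusters, 2 of 4 miR-148 and miR-152 members rose: miR-148b-5p, with no control read, by a fitted 3.46 (at least 4.88-fold) and miR-152-3p by 2.35. With centring or relative to the median 1 was higher, and with library totals 4 were. The miR-152-3p call was lost in 5 of 20 alternatives (adjusted p 0.00163 to 0.630), among them those without palmitic acid replicate 1 (0.0645), 2 (0.0766) or 3 (0.0905). miR-148b-3p stood at 1.53 (adjusted p = 0.109, and 2.25 with 0.0166 without control replicate 2; 0.0166 to 0.667 over its alternatives). In the miR-221 and miR-222 cluster 1 of 3 rose (miR-221-5p, with no control read, by a fitted 4.19 and at least 8.82-fold), and miR-221-3p (adjusted p = 0.0519) passed without control replicate 1, 2 or 3 (0.0166, 0.0342 and 0.0344; 0.00638 to 0.595 over its alternatives). The 1 tested member of the miR-34 and miR-449 family, miR-34a-5p, with no control read, rose. So did that of the miR-15 and miR-16 family, miR-16-5p (2.76, adjusted p = 0.0386). The miR-16-5p call was lost in 11 of 20 alternatives, among them those without control replicate 2, 0.0511, and palmitic acid replicate 1, 2 or 3, 0.0867, 0.126 and 0.121, with 0.0130 to 0.493 over all. Neither tested miR-181 member passed (miR-181a-5p at -1.34, and -3.67 with adjusted p = 0.00947 without control replicate 3, 0.00947 to 0.860 over its alternatives; miR-181b-5p at -0.14). In the Dlk1-Dio3 cluster 1 of 2 rose, miR-379-5p by 3.99, and 0 were higher relative to the median (miR-379-5p at 2.05, adjusted p = 0.0532). The miR-379-5p call was also lost in the voom fit (0.0898; 1.3e-04 to 0.0898 over its alternatives), and miR-541-5p stood at -0.56 (-2.30, adjusted p = 0.0206, without control replicate 3; 0.0206 to 0.932 over its alternatives). No member of the miR-322 to miR-503, Sfmbt2 intron or miR-290 to miR-295 clusters was abundant enough to be tested.

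Of the lists fixed by function, none passed the camera test, which had an unadjusted p below 0.05 for 2 of all lists; the fry test, which does not compare a list with other miRNAs, passed 15 of all lists. Among miRNAs linked to hepatic steatosis or lipotoxicity, 9 of 16 rose, with miR-21a-5p, miR-34a-5p and miR-29a-3p among them, and 2 fell, miR-122-5p and miR-128-3p (adjusted p = 0.635); relative to the median 5 were higher and 4 lower. For cholesterol and fatty acid metabolism 6 of 13 rose, among them miR-378a-3p by 4.45 (SE 0.75) and miR-26a-5p by 2.33 (SE 0.45), and the same 2 fell (adjusted p = 0.749), against 3 higher and 3 lower relative to the median and 8 and 1 with library totals. miR-26a-5p did not pass relative to the median (0.39, adjusted p = 0.485; 4.2e-05 to 0.485 over its alternatives). For endothelial function and inflammation 6 of 14 rose and 2 fell, with miR-21a-5p up, miR-10a-5p down and miR-126a-3p in neither direction (adjusted p = 0.607), against 6 higher and 4 lower relative to the median. In the p53-responsive list 4 of 7 rose, among them miR-34a-5p and miR-107-3p (4.34, SE 1.18, not past the threshold without palmitic acid replicate 1, adjusted p = 0.0546, or 3, 0.0526; 0.00410 to 0.119 over its alternatives), and 0 fell (adjusted p = 0.6002), against 2 higher and 1 lower relative to the median. Of 18 insulin signalling miRNAs 9 rose and 3 fell (adjusted p = 0.962), against 5 higher and 7 lower relative to the median and 11 and 0 with library totals. Of 4 inflammation-responsive miRNAs miR-21a-5p rose, miR-146a-5p fell and miR-146b-5p stood at -0.21 (adjusted p = 0.898), and 0 were lower with library totals. The 1 tested hypoxia-responsive miRNA, miR-199a-3p, did not pass, but was lower with upper-quartile scaling, centring and relative to the median. Some rises in these lists had no control read, so the filter fixed their direction. For endothelial function and inflammation these were miR-17-5p, miR-31-3p, miR-34a-5p and miR-221-5p. They were miR-34a-5p and miR-192-3p for steatosis and for p53, miR-96-5p for cholesterol, and miR-29c-5p for insulin signalling. Counts adjusted over the list alone were the same for every list but these: 3 epithelial miRNAs, 4 of the miR-29 family, 5 of the miR-17 to miR-92 clusters, 2 of the miR-221 and miR-222 cluster and 7 of the endothelial function list were then higher, and 2 erythroid miRNAs lower.

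Arm usage, the log2 ratio of the 5p to the 3p arm of a hairpin, differed for 9 of 24 hairpins. For mir-30a it shifted toward the 5p arm by 4.93 (SE 1.38, adjusted p = 0.0125) and for mir-30e by 3.63 (SE 1.32, adjusted p = 0.0420), while for mir-122 it shifted toward the 3p arm by -4.66 (SE 1.04, adjusted p = 0.00630) and for mir-193a by -6.54 (SE 1.59, adjusted p = 0.00862). The others were mir-151 (4.85), mir-22 (4.65), let-7d (4.48), mir-122b (3.66) and mir-192 (-3.73). Control reads of 1 arm were few for several hairpins, 0 in each control for miR-192-3p and 0 in at least 1 control for both arms of mir-193a, miR-151-5p and miR-22-5p, so these 4 changes depend on the value given to 0 reads. As the mir-122 and mir-122b hairpins overlap, their 2 shifts are not separate results. The count was 2, 0 and 5 hairpins without palmitic acid replicate 1, 2 and 3, and 4 where each arm had a mean of at least 50.

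**Figure D4:**
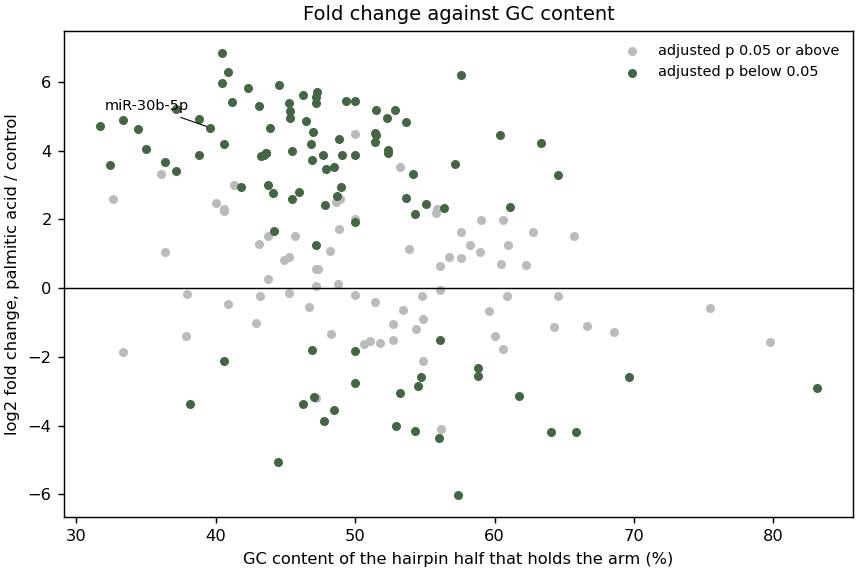
Log2 fold change, palmitic acid over control (vertical axis), against GC content in percent (horizontal axis), for the 174 tested miRNAs with a matched hairpin. GC content is that of the hairpin side that holds the arm, or of the whole hairpin where a name gives no arm. Fold changes were lower at higher GC content (Spearman rho = -0.38), and miR-30b-5p lies at 39.6% GC.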

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

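Thinned reads, a pseudocount of 5, centred libraries, changes relative to the median and GC correction were chosen after the data were seen; the other alternatives were set before. A Wald test on counts was not run, as the table holds no counts; summing rows of one name and dropping other rows gave no value, since there are none. miR-30b-5p passed in all 20 of its alternatives (2.73 to 5.61, adjusted p 5.6e-05 to 0.00519). None of the 102 miRNAs called as deposited was called in the other direction under these alternatives. miR-24-3p and miR-27a-3p, not called as deposited, were higher with the GC trend removed (1.81 and 1.99) and lower relative to the median. The number of higher miRNAs stayed within 1.5 times of 76 except for 48 relative to the median; the number of lower ones was 10 with library totals, 60 with no filter, 40 after centring and 59 relative to the median, which by construction moves all changes by 1.94. Leaving out 1 library gave 63 to 85 higher and 20 to 32 lower. Without a filter, 1058 miRNAs were tested and 59.5% of calls were higher, against 74.5%; library totals gave 90.6%. Among named miRNAs that passed with either scale, the sign turned relative to the median for miR-30d-5p (-1.82), miR-126a-3p (-1.87), miR-92a-3p (-1.39), miR-27b-3p (-0.68), miR-24-3p (-1.06) and miR-27a-3p (-1.25). Of the 49 named miRNAs that passed, 28 passed under every alternative. With an estimated correlation 0 lists passed, and 15 with fry, which does not compare lists with other miRNAs; fry pointed up for the let-7 and miR-98 family (adjusted p = 0.0296), opposite to camera. Arm calls numbered 4 at a mean of at least 50, where fewer hairpins are tested, and 0 to 11 without 1 library, where fewer libraries are; the cause was not tested further. The share difference was -54.4 points for miR-122-5p, which has the highest mean over all libraries, -1.03 for the 50 highest by that mean and -12.4 to -6.13 without 1 library; the detected difference was 52.2 at 5 reads, 337 at full depth and 108 to 213 without 1 library. Equal replicate numbers correlated at 0.209, 0.151 and 0.038 between groups, all positive, but control replicate 3 correlated best with palmitic acid replicate 2 (0.062). Whether equal numbers mark a pairing thus stays open, and the labels do not say. With the replicate block 83 were higher and 28 lower, miR-30b-5p stood at 4.67, 1 list passed and 5 hairpins differed. The miR-122-5p call was not made with the block (adjusted p = 0.105), nor with the block and GC correction (0.0581). Depth limits low miRNAs most in controls, where 1 read is worth 1.37 to 1.54 on the log2 scale.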

Other observations

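Thinning, centring, changes relative to the median and removal of the GC trend were chosen after the data were seen, and the tests of scaling and of GC content as a contribution after the results they measure. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 102 miRNAs and no other split called any, so that 1 of the 10 splits gave as many. For lists, 5 of the 10 gave as many as the real split, which gave 1, the highest of the others being 1. For arm ratios 1 of the 10 did, with 9 hairpins against 0 in the others.

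Fold changes followed GC content. Among 87 miRNAs under the median GC content 49 rose and 8 fell, with a median log2 change of 2.95, and among 87 at or above it 26 rose and 17 fell, with a median of 0.69. The trend was present among the 158 with at least 1 control read (rho = -0.37). The sign was the same within 10 let-7 and miR-98 members, 5p arms and let-7j (rho = -0.43, permutation p = 0.22), which is not past a threshold. The name let-7j gives no arm, so its GC content (34.4%, the lowest of the 10) is that of the whole hairpin. GC-dependent recovery between the groups may have contributed to the fold changes (rho = -0.38). After a linear trend of each library was removed 97 miRNAs passed. The removal keeps the mean change over all miRNAs, with a median log2 change of 1.97 after it. Calls that rest on that change could not be lost, so this count cannot decide on such a trend as the whole cause. The GC content was taken from the hairpin and not from the mature sequence, so a GC effect may have been removed only in part. GC-dependent recovery as the whole cause is therefore not excluded. A difference through the treatment itself stays open, as untested.

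The rise of miR-30b-5p was weighed against GC content and depth. After the GC trend was removed it was 3.36 (SE 0.54, adjusted p = 0.0011), against 4.67 before. After reads were thinned to the effective depth of the shallowest library it was 4.53 as the median of the draws (4.36 to 4.94, adjusted p = 2.6e-04). Thinning leaves the expected ratio of the groups unchanged, so the thinned value cannot decide on shallow controls as a cause. It shows only that the rise was also present at equal effective depth. The GC correction keeps the mean change over all miRNAs, so the corrected value cannot decide on a linear trend with hairpin GC content as the whole cause. The GC content of the mature sequences was not used, so GC-dependent recovery is not excluded. What also stays open is a difference between preparations of vesicles that goes with the groups, which the labels do not describe, beside the treatment itself.

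More miRNAs were higher than lower, 74.5% of calls. Thinning left 75.2% over 181 tested miRNAs, the number chosen at full depth. The 17 without a control read, whose direction the filter fixed, had entered by that choice. Thinning after it thus cannot decide on shallow controls as the cause. Centring each library on its median gave 61.9%, between the bounds set for the test, and the change relative to the median, which places as many miRNAs above as below by construction, gave 44.9%. No spike-in or other external reference was used here, so a scaling of the deposited values and a true excess of higher miRNAs cannot be told apart. A difference through the treatment itself stays open.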
